A study of Mus musculus with 24 samples.

How the data were processed

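Livers of 24 male F1 hybrid mice (C57BL6J by FVBN) were profiled by sequencing of polyadenylated RNA, with 4 libraries in each of 6 groups. Wild-type mice were fed freely to 16 weeks, fed freely to 104 weeks, or restricted by 30% to 16 weeks. Ercc1Δ/− mice, which carry a truncated and a null allele of the DNA repair gene Ercc1 and age prematurely, were fed freely to 7 or 16 weeks, or restricted by 30% to 16 weeks. The labels give a daily intake of 3.0 g for the wild type and 2.3 g for the mutant. Restriction began at 7 weeks of age with 10%, was raised by 10% each week, and stood at 30% from 9 weeks, at 2.1 g a day for the wild type and 1.6 g for the mutant. Food was given shortly before the dark phase, but not on the day of sacrifice before the livers were taken. RNA was isolated with a DNase step, and libraries were made by a commercial provider, per the labels' protocols. The labels number the samples of a group without stating in words that each is a separate animal, so p-values measure the spread between these samples.

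The deposited table holds raw counts per gene and library, with no normalization. Per the submitters' processing notes, the tools were Trimmomatic 0.39, STAR 2.7.0f and featureCounts of Subread 1.6.4, with genome build GRCm38.p6. The annotation release, the treatment of multi-mapped reads and whether counting used strand are not given in the sources used here. All 22429 genes of the table were matched by identifier to GENCODE M21 on GRCm38, from which positions and symbols were taken. Of these, 21834 were protein-coding and 494 were immunoglobulin or T cell receptor genes, and 3497 had no count in any library. The deposited length column equalled the annotated genomic span in 97.8% of genes, so it was used as a span and not as a transcript length. Genes with near-identical copies (Mup, Scd, Cyp2b, Cyp3a41, Cyp4a, Acot, Sult, Saa, hemoglobin and ribosomal protein genes with pseudogenes) may share reads and their separate values are uncertain. Total counts ran from 13.3 to 20.6 M (mega) per library.

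Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the groups given, which left 12690, and library sizes were scaled by TMM. A single model with a mean for each of the 6 groups was fitted to all 24 libraries (18 residual degrees of freedom, common dispersion 0.0493), and each comparison was tested with edgeR's quasi-likelihood F test with robust estimation. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. Of the 8 contrasts, 6 compare a pair of groups and 2 test whether the effect of restriction or of age differs between genotypes. Levels are CPM on TMM-scaled library sizes, and log2 fold changes carry standard errors. A ratio against a group with 1 to 3 counts in all is given with its 95% counting interval, and one against 0 counts as a lower bound against 3 counts over the group. Such intervals and bounds cover counting error only.

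Gene lists for 38 pathways, hormone responses and cell types were fixed before the data were examined, as were the 8 contrasts, their tests and the rule for naming genes. They cover translation, stress and repair, hormones and sex bias, metabolism, the clock, zonation, inflammation, cell types and proliferation. Each list was tested with camera of limma 3.58.1 at its preset correlation of 0.01, adjusted over the lists within a contrast, and again with an estimated correlation and with fry, which asks whether the members move in a common direction. For each comparison of groups, the rule named the 5 largest rises and 5 largest falls among called genes with a mean CPM of at least 2, no overlap between groups and a symbol that is not a model name. It then took up to 3 called members of each list in order of camera p until about 30 genes were reached. For the 2 interactions it took 3 and 3 genes and 1 member per list. Some genes the rule named are not reported here, though counts include them. To these were added 15 genes given wherever they bear on a comparison, among them Ercc1, Cdkn1a, Gdf15, Ghr, Igf1, Fgf21, Cyp4a14, Mup20 and Rps6.

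Similarity of 2 comparisons was measured as the correlation of log2 fold changes across genes, which are not independent replicates, and as the overlap of calls beside that of independent lists. Where 2 comparisons share a group, 20 simulations without effects gave the chance value, and the shared libraries were also split 2 and 2. The trend with gene span was the slope of log2 CPM (pseudocount 0.1 CPM), centred per gene, on log10 span for each library. Slopes were compared between groups of 4 with two-sided exact permutation tests over 70 relabellings, adjusted over 6 comparisons, and 0.0286 is the smallest p they can give. No 2 libraries of a group agreed within counting noise (lowest chi-square per degree of freedom 8.32).

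The steps were tested on simulated counts with the means and sizes of the freely fed 16-week comparison. Over 12690 genes edgeR recovered 22.4% of 67 genes changed by 1.5-fold, 71.6% of 67 changed by 2-fold and 86.4% of 66 changed by 4-fold, and called 4 of 12450 unchanged genes. DESeq2 recovered 29.9%, 80.6% and 92.4% and called 12 unchanged genes. An interaction of 4-fold was recovered in 82% of genes given one, with 12 unchanged genes called, and a slope difference of -0.2 was found as -0.194. Alternatives were other scalings (RLE, upper quartile), other filters on low counts, removal of the 20 most abundant genes, the replicate number as a block, only the groups of a contrast in the fit, limma-voom, DESeq2 1.42.0, a fold threshold, and leaving out each library in turn. Figures and slopes were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.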

Results

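Liver RNA of male mice was compared by genotype, age and food intake in 24 libraries, 4 per group. Total counts per library averaged 16.6 ± 2.24 M (SD, n = 4) in freely fed wild-type mice at 16 weeks, 16.4 ± 2.67 M in restricted wild-type mice and 14.3 ± 0.828 M in wild-type mice at 104 weeks. In the Ercc1Δ/− mutant, a progeroid DNA repair mutant, they averaged 17.8 ± 2.86 M at 7 weeks, 15.5 ± 1.45 M at 16 weeks and 15.5 ± 1.74 M after restriction. Albumin was the most abundant gene in all 24 libraries, at 10.5 ± 1.35% of counts in restricted wild-type liver and 4.95 ± 1.05% at 104 weeks. Transcripts of mitochondrial DNA made up 13.9 ± 2.07% and 14.1 ± 0.653% of counts in the restricted wild type and mutant, and between 9.40 ± 0.738% and 11.1 ± 0.465% in the freely fed groups. Below, levels are CPM as mean ± SD over the 4 libraries of a group, and log2 fold changes are given ± SE.

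The 500 most variable genes separated the libraries first by diet and then by genotype. Principal component 1 held 43.7% of the variance, with the 8 restricted libraries between 19.2 and 42.9 and the 16 freely fed libraries between -27.1 and -7.74. Component 2 held 22.8%, with the 12 mutant libraries between 8.93 and 23.4 and the 12 wild-type libraries between -22.8 and -13.0.

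**Figure D1:**
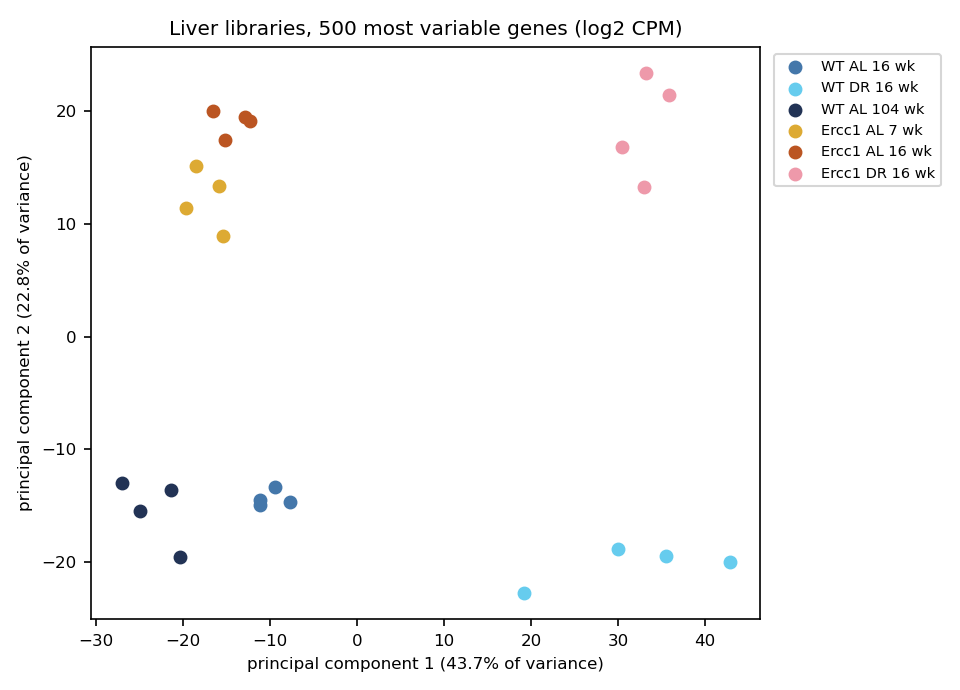
Each point is a liver library on principal components 1 and 2 of log2 CPM of the 500 most variable genes, coloured by group (n = 4 each). Restricted libraries lie at 19.2 or higher on component 1, and mutant libraries at 8.93 or higher on component 2.

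Ercc1 (ENSMUSG00000003549, chromosome 7, 19344778 to 19356524 on GRCm38), the targeted gene, which encodes a subunit of the endonuclease that cuts 5' of DNA lesions, was measured at a low level in every library. It stood at 2.59 ± 0.413 CPM in wild-type liver at 16 weeks, 3.52 ± 0.977 CPM after restriction and 3.11 ± 0.756 CPM at 104 weeks. In the mutant it stood at 1.61 ± 0.488 CPM at 7 weeks, 1.51 ± 0.414 CPM at 16 weeks and 1.55 ± 0.331 CPM after restriction. Ercc1 was lower in the restricted mutant than in the restricted wild type (log2 fold change -1.19 ± 0.27, edgeR adjusted p = 0.0033). On free feeding the difference did not pass the threshold (log2 fold change -0.78 ± 0.28, edgeR adjusted p = 0.0754). Gene-level counts do not show which part of the transcript the reads cover, so reads from the mutant alleles are included.

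Mutant and wild-type liver were compared at 16 weeks on free feeding, where the mutant also ate less (2.3 against 3.0 g a day). Called interferon-response genes and most called p53 targets, which respond to nucleic acids or cytokines and to DNA damage, were higher in the mutant. Called genes of fatty acid oxidation and most changed female-biased liver genes were lower. With an estimated correlation only the female-biased list of these 4 kept its call. Irf7, a transcription factor that amplifies the interferon response, stood at 48 ± 11 against 10.8 ± 2.55 CPM (log2 fold change 2.16 ± 0.21, edgeR adjusted p = 1.35e-07), and Cyp2b10, a drug-metabolising enzyme induced through the receptor CAR, at 0.489 ± 0.217 against 23.8 ± 8.04 CPM (log2 fold change -5.58 ± 0.58, adjusted p = 1.64e-06). In all, 1262 of 12690 genes were called changed, 647 higher and 615 lower, and 594 of them by more than 1 on the log2 scale.

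The largest rises under the naming rule were those of Igsf23 (chromosome 7, 19937305 to 19950756; log2 fold change 6.33 ± 0.55, edgeR adjusted p = 5.68e-08), Cib3, Gpx6, a glutathione peroxidase gene, Tff3, a secreted trefoil peptide, and Slc13a5, a citrate transporter, with log2 fold changes between 4.38 and 6.33. Igsf23 lies 0.581 Mb from Ercc1 on the same chromosome. Among the largest falls were Cyp2b10, Cyp2b13, Cyp2b9 and Cyp2b23, which lie in a cluster of similar genes and can share reads. In the interferon list 19 of 35 tested members rose and 0 fell (24 and 0 adjusted over the list alone), among them Usp18, which removes ISG15 from proteins (3.23 ± 0.33, edgeR adjusted p = 5.18e-07), and Oas1a, a sensor of double-stranded RNA (2.84 ± 0.33, adjusted p = 3.09e-06). The list gave camera adjusted p = 1.23e-18, and 0.113 with an estimated correlation. In the p53 target list 15 of 30 tested members rose and 1 fell (18 and 2 adjusted over the list alone). It gave camera adjusted p = 9.49e-09, and 0.0824 with an estimated correlation. Phlda3 stood at 9.44 ± 8.91 against 0.87 ± 0.245 CPM (log2 fold change 3.42 ± 0.55, edgeR adjusted p = 1.78e-04) and Ccng1 at 46.6 ± 13.9 against 20.8 ± 1.46 CPM (log2 fold change 1.16 ± 0.21, adjusted p = 6.58e-04), while the death receptor gene Tnfrsf10b rose by 3.29 ± 0.60 on the log2 scale. Gdf15, a stress-induced hormone, rose (log2 fold change 1.92 ± 0.41, edgeR adjusted p = 0.00351). Cdkn1a, the p53-induced cell cycle inhibitor, had log2 fold change 1.04 ± 0.55, edgeR adjusted p = 0.257. In the macrophage and Kupffer cell marker list 11 of 26 tested members rose and 0 fell (14 and 0 adjusted over the list alone). It gave camera adjusted p = 7.69e-07, and 0.432 with an estimated correlation. Other passing markers included erythroid, with a median of -1.63 (camera adjusted p = 0.00455, and 0.308 with an estimated correlation). B and plasma cell markers had 1.51 (camera adjusted p = 0.0101, and 0.35 with that correlation). Pericentral markers had 0.47 (camera adjusted p = 3.09e-05, and 0.0824 with that correlation), and periportal ones a mean of -0.246. The B cell call was lost without mutant replicate 4 (camera adjusted p = 0.054). Folds given here moved by over 1.5 times, on the log2 scale to 2.497 for Phlda3 and 2.60 for Tnfrsf10b without mutant replicate 1, 5.09 for Slc13a5 without wild-type replicate 3 and 7.67 for Igsf23 without wild-type replicate 4.

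Among genes of fatty acid oxidation and other PPARalpha targets, 0 of 43 tested members rose and 19 fell (0 and 25 adjusted over the list alone). The list gave camera adjusted p = 5.10e-15, and 0.122 with an estimated correlation. Fabp1, the fatty acid binding protein of liver, stood at 2021 ± 375 against 5220 ± 922 CPM (log2 fold change -1.37 ± 0.17, edgeR adjusted p = 7.45e-06), Acaa1b, a peroxisomal thiolase, had log2 fold change -1.83 ± 0.26, adjusted p = 4.13e-05. Cyp4a14, a fatty acid hydroxylase, had log2 fold change -2.72 ± 0.50, edgeR adjusted p = 0.00119. In the lipogenesis list 0 of 24 tested members rose and 6 fell (0 and 10 adjusted over the list alone). The lipogenesis list gave camera adjusted p = 3.69e-07, and 0.293 with an estimated correlation. Scd1, the stearoyl-CoA desaturase, fell from 2652 ± 671 to 227 ± 88.1 CPM (log2 fold change -3.54 ± 0.43, edgeR adjusted p = 9.83e-06), with reads that its paralogs may share. Fasn, fatty acid synthase, had log2 fold change -0.16 ± 0.58, edgeR adjusted p = 0.907. In the cholesterol synthesis list 9 of 26 tested members rose and 0 fell (16 and 0 adjusted over the list alone), and Sqle, squalene epoxidase, stood at 61.5 ± 8.68 against 3.56 ± 0.315 CPM (log2 fold change 4.11 ± 0.54, edgeR adjusted p = 3.15e-05). That list gave camera adjusted p = 1.63e-08, and 0.353 with an estimated correlation. Female-biased liver genes fell in 16 of 34 cases and rose in 3 (20 and 6 adjusted over the list alone), a call that held with camera adjusted p = 5.00e-13, and 0.0385 with an estimated correlation. Cyp2c39 fell to 60.0 ± 4.01 from 372 ± 35.5 CPM (log2 fold change -2.63 ± 0.21, edgeR adjusted p = 2.38e-08). In the male-biased list 10 of 29 tested members rose and 2 fell (10 and 3 adjusted over the list alone). The male-biased list gave camera adjusted p = 0.0122, and 0.497 with an estimated correlation. Mup20, a urinary pheromone protein, rose (log2 fold change 2.04 ± 0.39, edgeR adjusted p = 0.00155). Ghr, the growth hormone receptor, fell (log2 fold change -0.66 ± 0.17, edgeR adjusted p = 0.0107). Igf1 had log2 fold change -0.07 ± 0.14, edgeR adjusted p = 0.812.

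For translation, 19 of 77 tested members rose and 0 fell (49 and 0 adjusted over the list alone) in the list of cytosolic ribosomal proteins, with a median log2 fold change of 0.38 and camera adjusted p = 1.15e-13, and 0.433 with an estimated correlation. Rpl3 stood at 291 ± 28.4 against 198 ± 21.8 CPM (log2 fold change 0.56 ± 0.12, edgeR adjusted p = 0.00398). Rps6 had log2 fold change 0.36 ± 0.12, edgeR adjusted p = 0.0591. In ribosome biogenesis 11 of 47 tested members rose and 0 fell (17 and 0 adjusted over the list alone). That list gave camera adjusted p = 9.23e-08, and 0.433 with an estimated correlation. Eef1a1, the main elongation factor, had log2 fold change 0.18 ± 0.11, edgeR adjusted p = 0.33. Eif4ebp1, a repressor of cap-dependent translation, had log2 fold change 0.18 ± 0.17, edgeR adjusted p = 0.573. With only the 8 libraries of this comparison in the fit, 2202 genes were called.

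**Figure D2:**
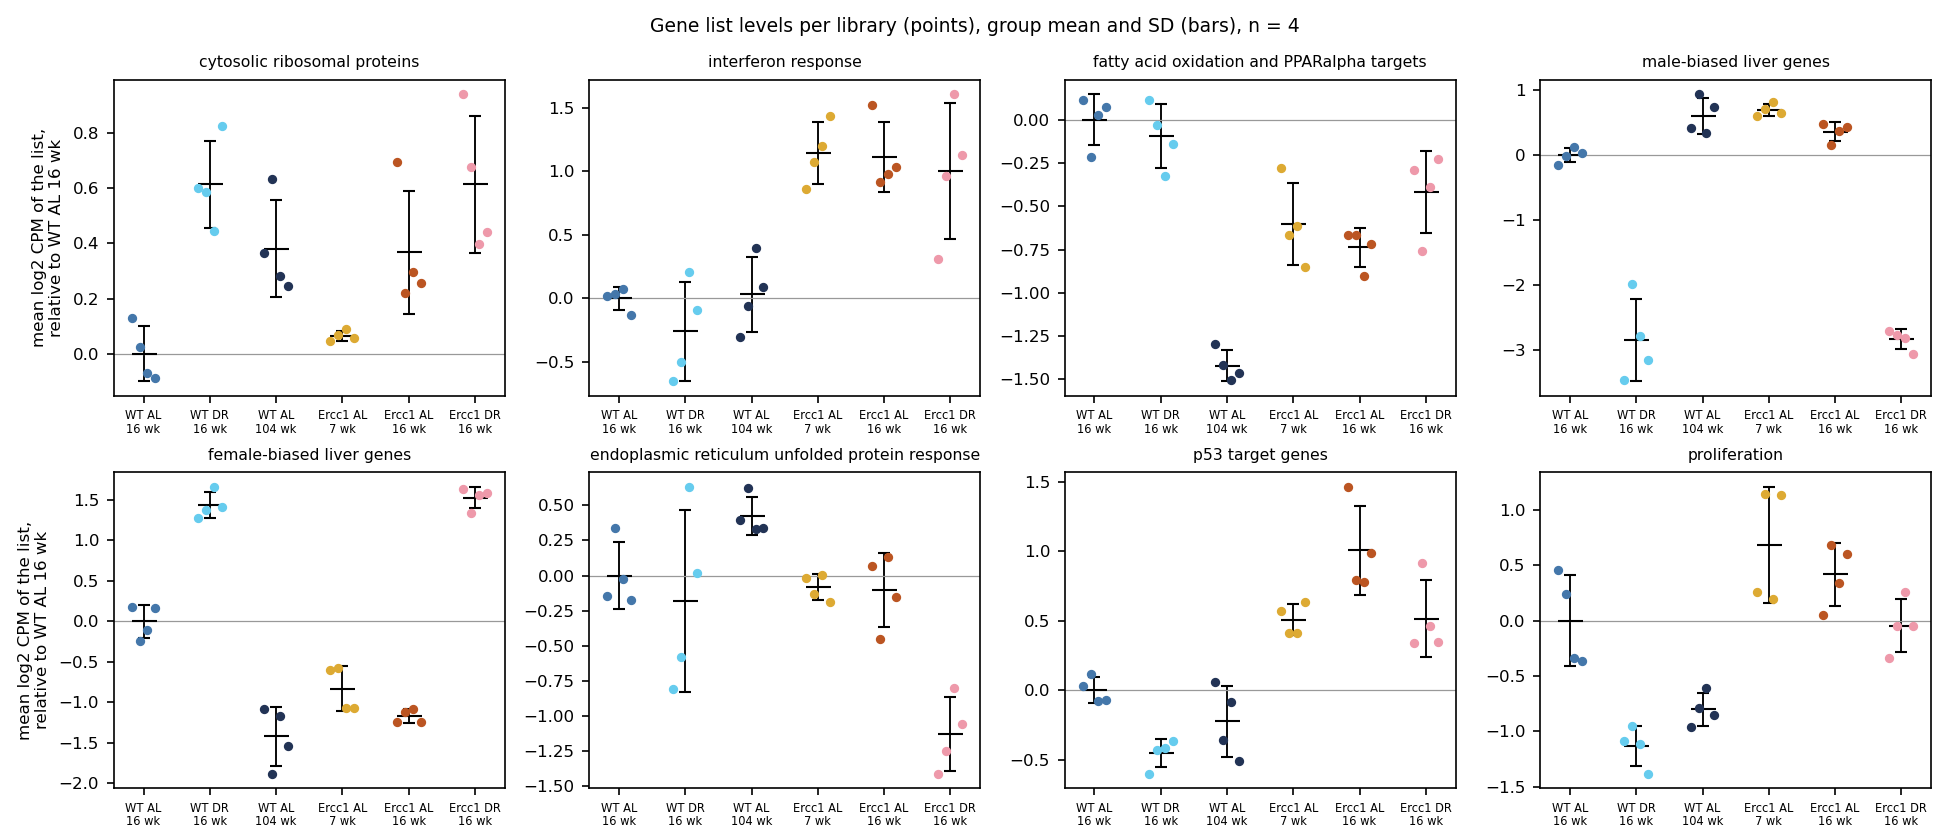
Each panel gives the mean log2 CPM of a gene list's members per library (points), relative to freely fed wild-type liver at 16 weeks, with the group mean and SD (bars, n = 4). Interferon and p53 lists are higher in mutant groups, the fatty acid oxidation list is lowest at 104 weeks, and male-biased genes are lowest in both restricted groups.

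Under restriction the same genotypes were compared to ask which differences remain when both eat less. Called interferon, macrophage and proliferation genes were higher in the restricted mutant, and called genes of the unfolded protein response were lower. All 4 list calls were lost with an estimated correlation. Irf7 stood at 42 ± 8.35 against 7.27 ± 0.6 CPM (log2 fold change 2.53 ± 0.21, edgeR adjusted p = 2.86e-08), and Cd68, a lysosomal protein of macrophages, at 7.57 ± 0.535 against 2.46 ± 0.694 CPM (log2 fold change 1.64 ± 0.23, adjusted p = 2.95e-05). Hsp90b1, a chaperone of the endoplasmic reticulum, stood at 625 ± 153 against 1553 ± 783 CPM (log2 fold change -1.31 ± 0.26, edgeR adjusted p = 0.00101). A total of 2320 genes were called, 1216 higher and 1104 lower, and 998 of them by more than 1 on the log2 scale.

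Gpx6 (log2 fold change 6.18 ± 0.46, edgeR adjusted p = 1.10e-08), Tmprss4, a membrane serine protease (log2 fold change 5.79 ± 0.60, adjusted p = 4.16e-07), Igsf23 (5.64 ± 0.51, adjusted p = 6.35e-08) and Dnah1, an axonemal dynein chain (6.32 ± 1.05, adjusted p = 2.08e-04), were among the largest rises. Lrtm2 had 457 counts over the mutant libraries and 2 over the wild type, a ratio of 222 with a 95% counting interval from 61.1 to 1838. The largest falls were Ephb6 (log2 fold change -4.19 ± 0.54), Dio1, which converts thyroxine to its active form (-3.75 ± 0.49), Slc17a8, Serpina12 and Nrp2, a semaphorin receptor, which went from 25.6 ± 3.37 to 2.68 ± 0.437 CPM (log2 fold change -3.25 ± 0.28, edgeR adjusted p = 3.67e-08). In the interferon list 23 of 35 tested members rose and 0 fell (25 and 0 adjusted over the list alone), and in the macrophage list 19 of 26 tested members rose and 0 fell (19 and 0 adjusted over the list alone). These gave camera adjusted p = 2.00e-15, and 0.224 with an estimated correlation for interferon genes and camera adjusted p = 3.36e-14, and 0.245 with an estimated correlation for macrophage markers. C1qb, a complement component made by macrophages, had log2 fold change 1.25 ± 0.20, edgeR adjusted p = 1.11e-04. In the proliferation list 15 of 35 tested members rose and 0 fell (17 and 0 adjusted over the list alone). It gave camera adjusted p = 1.60e-07, and 0.361 with an estimated correlation. Cdc20, an activator of the anaphase-promoting complex (4.03 ± 0.62, edgeR adjusted p = 5.77e-05), and Ccne1, cyclin E1 (3.13 ± 0.50, adjusted p = 1.01e-04) were among its members. In the p53 target list 13 of 30 tested members rose and 1 fell (14 and 1 adjusted over the list alone). It gave camera adjusted p = 1.25e-05, and 0.224 with an estimated correlation. Gtse1 rose (log2 fold change 4.21 ± 0.50, edgeR adjusted p = 2.96e-06), Ckap2 had 112 counts against 2 (ratio 54.4, interval 14.7 to 454.7), Gdf15 had log2 fold change 1.78 ± 0.41, adjusted p = 0.0041 and Cdkn1a 1.43 ± 0.56, adjusted p = 0.0806. Folds given here moved by over 1.5 times, on the log2 scale to -4.37 for Dio1 and 5.72 for Dnah1 without mutant replicates 1 and 3, and to 8.22 for Dnah1 and 5.0 for Gtse1, 6.85 for Tmprss4 and 6.98 for Gpx6 without wild-type replicates 2, 3 and 4.

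In the list of the unfolded protein response, 0 of 25 tested members rose and 18 fell (0 and 21 adjusted over the list alone), with Pdia4 at log2 fold change -1.70 ± 0.32, edgeR adjusted p = 7.25e-04 and Ero1b at log2 fold change -1.47 ± 0.26, adjusted p = 2.65e-04 (camera adjusted p = 9.43e-10, and 0.361 with an estimated correlation). In the cytosolic heat shock list 0 of 18 tested members rose and 9 fell (0 and 10 adjusted over the list alone), and Stip1 had log2 fold change -1.04 ± 0.19, edgeR adjusted p = 3.90e-04. That list gave camera adjusted p = 1.25e-05, and 0.367 with an estimated correlation. In lipogenesis 0 of 24 tested members rose and 9 fell (0 and 11 adjusted over the list alone). The lipogenesis list gave camera adjusted p = 7.79e-05, and 0.367 with an estimated correlation. Dgat2, which makes triglyceride (-0.94 ± 0.11, edgeR adjusted p = 3.10e-06), and Mlxipl, the carbohydrate-response factor ChREBP (-1.22 ± 0.23, adjusted p = 4.81e-04), were lower. Of the pericentral hepatocyte markers 9 of 18 tested members rose and 1 fell (9 and 1 adjusted over the list alone). The pericentral list gave camera adjusted p = 2.12e-04, and 0.224 with an estimated correlation. PPARalpha targets went both ways, since 3 of 43 tested members rose and 20 fell (3 and 20 adjusted over the list alone). The list gave camera adjusted p = 3.08e-04, and 0.495 with an estimated correlation. Ghr was lower in the mutant here too, at 106 ± 10.9 against 213 ± 72.8 CPM (edgeR adjusted p = 1.41e-04). The ribosomal protein list did not pass in this comparison, with a median log2 fold change of -0.01 and camera adjusted p = 0.992. With only these 8 libraries in the fit 877 genes were called, and Fgf21, the fasting hormone (-1.80 ± 0.47, edgeR adjusted p = 0.00849), lost its call without wild-type replicate 1 (-1.01, adjusted p = 0.0914).

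Natural ageing was measured as wild-type liver at 104 against 16 weeks, both on free feeding. Called fatty acid oxidation genes fell, led by Cyp4a hydroxylases, and called immunoglobulin, neutrophil and acute-phase genes rose. The acute-phase list lost its call with an estimated correlation. Cyp4a10 (chromosome 4, 115518264 to 115533649), a PPARalpha-dependent fatty acid hydroxylase, went from 799.9 ± 269 to 34 ± 16.1 CPM (log2 fold change -4.56 ± 0.37, edgeR adjusted p = 3.21e-08). Igkc, the kappa light chain constant region, went from 0.676 ± 0.235 to 13.8 ± 1.41 CPM (log2 fold change 4.35 ± 0.51, edgeR adjusted p = 4.35e-06). The clock repressor gene Nr1d1 rose as well (log2 fold change 3.75 ± 0.40, edgeR adjusted p = 1.85e-06). In total 1286 genes were called, 651 higher and 635 lower, and 589 of them by more than 1 on the log2 scale.

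Of the fatty acid oxidation and PPARalpha list, 0 of 43 tested members rose and 30 fell (0 and 34 adjusted over the list alone). The list gave camera adjusted p = 2.64e-47, and 0.00282 with an estimated correlation, so the call held. Cyp4a14 had log2 fold change -5.41 ± 0.57, edgeR adjusted p = 3.53e-06, and Cyp4a29, Cyp4a31 and Cyp4a32 had log2 fold changes of -4.71, -4.06 and -3.50, with reads these similar genes may share. Fgf21, a PPARalpha-dependent hormone, also fell (log2 fold change -2.83 ± 0.49, edgeR adjusted p = 5.16e-04). Female-biased liver genes fell in 18 of 34 cases and rose in 3 (18 and 3 adjusted over the list alone), which held with camera adjusted p = 2.21e-21, and 0.00167 with an estimated correlation. Fmo2 (log2 fold change -3.17 ± 0.24, edgeR adjusted p = 4.55e-09) and Cyp3a41a (log2 fold change -2.93 ± 0.22, adjusted p = 4.55e-09) were examples, while in the male-biased list 11 of 29 tested members rose and 2 fell (12 and 2 adjusted over the list alone). The male-biased list gave camera adjusted p = 1.87e-05, and 0.318 with an estimated correlation. Hsd3b5 had log2 fold change 1.62 ± 0.39, edgeR adjusted p = 0.0103.

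In the B and plasma cell list 7 of 8 tested members rose and 0 fell (7 and 0 adjusted over the list alone). The B cell list gave camera adjusted p = 1.14e-11, and 0.00282 with an estimated correlation, so the call held. Ighg2b, an immunoglobulin heavy chain region, had log2 fold change 4.32 ± 0.74, edgeR adjusted p = 3.85e-04, and 5.04 without replicate 3 at 16 weeks. Ighg2c had 89 counts against 3, a ratio of 35.8 with an interval from 11.9 to 177. Of the neutrophil markers 4 of 5 tested members rose and 0 fell (4 and 1 adjusted over the list alone). The neutrophil list gave camera adjusted p = 3.73e-04, and 0.0117 with an estimated correlation, so the call held. Of the macrophage markers 5 of 26 tested members rose and 0 fell (11 and 0 adjusted over the list alone). The macrophage list gave camera adjusted p = 7.07e-07, and 0.405 with an estimated correlation. The scavenger receptor Marco had log2 fold change 3.07 ± 0.58, edgeR adjusted p = 0.00133 and lysozyme Lyz2 had log2 fold change 1.40 ± 0.28, adjusted p = 0.00152. In the acute phase list 12 of 31 tested members rose and 0 fell (20 and 0 adjusted over the list alone). The acute phase list gave camera adjusted p = 1.58e-09, and 0.318 with an estimated correlation. Socs3, a feedback inhibitor of cytokine signals (2.80 ± 0.45, edgeR adjusted p = 2.54e-04), and Il1r1, the interleukin 1 receptor (2.46 ± 0.50, adjusted p = 0.00317) were among its members. The chemokine Cxcl1 stood at 42.8 ± 24.9 against 1.35 ± 0.757 CPM (log2 fold change 4.99 ± 0.53, edgeR adjusted p = 1.96e-06), and the immediate-early factor Junb rose with a wide spread (log2 fold change 3.65 ± 0.53, adjusted p = 1.32e-04, and 2.74 without replicate 1 at 104 weeks). The interferon list had 3 of 35 members higher and did not pass (camera adjusted p = 0.604), and the p53 list did not pass either (camera adjusted p = 0.17). The clock list did not pass as a whole (camera adjusted p = 0.17), with a median of -0.03, a mean of 0.15 and a test pointing down, while 4 members rose and 5 fell.

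In the ribosomal protein list 20 of 77 tested members rose and 0 fell (60 and 0 adjusted over the list alone). This list gave camera adjusted p = 4.42e-16, and 0.405 with an estimated correlation. Rpl27a had log2 fold change 0.63 ± 0.13, edgeR adjusted p = 0.00272. Of the cytosolic aminoacyl-tRNA synthetases 8 of 22 tested members rose and 0 fell (15 and 0 adjusted over the list alone). The list gave camera adjusted p = 2.22e-08, and 0.318 with an estimated correlation. In the unfolded protein response list 2 of 25 tested members rose and 0 fell (2 and 0 adjusted over the list alone), with camera adjusted p = 3.22e-04, and 0.561 with an estimated correlation, and endothelial markers had a median of -0.41 (camera adjusted p = 6.91e-04, and 0.584 with an estimated correlation). Seryl-tRNA synthetase Sars had log2 fold change 0.68 ± 0.12, edgeR adjusted p = 3.98e-04 and Cars had log2 fold change 0.95 ± 0.17, adjusted p = 5.42e-04. Of the proliferation genes 2 of 35 tested members rose and 8 fell (2 and 18 adjusted over the list alone). The proliferation list gave camera adjusted p = 7.07e-07, and 0.322 with an estimated correlation. Cdk1, the mitotic kinase, had log2 fold change -2.33 ± 0.48, edgeR adjusted p = 0.00271, and Ccne1 went the other way (2.19 ± 0.44, adjusted p = 0.00174). Rps6 had log2 fold change 0.48 ± 0.12, edgeR adjusted p = 0.0115, Eef1a1 0.41 ± 0.11, adjusted p = 0.0215 and Eif4ebp1 0.54 ± 0.17, adjusted p = 0.0425, and each of these 3 calls was lost on leaving out at least 1 library (highest adjusted p 0.054, 0.0711 and 0.114). The count fell to 792 without wild-type replicate 3 at 16 weeks.

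Mutant liver was compared at 16 against 7 weeks, with no 7-week wild type to set apart maturation. Cyp26a1 was higher at 16 weeks, and the drug-metabolising enzymes Cyp2c29 and Cyp3a11 were lower. Cyp26a1 (chromosome 19, 37697798 to 37701536), the enzyme that clears retinoic acid, rose from 0.913 ± 0.17 to 13.6 ± 3.26 CPM (log2 fold change 3.89 ± 0.33, edgeR adjusted p = 2.25e-07). Cyp2c29, induced through CAR, fell from 347 ± 68.1 to 108 ± 13.9 CPM (log2 fold change -1.68 ± 0.17, edgeR adjusted p = 5.20e-06). Only 87 genes were called by edgeR, 45 higher and 42 lower, with 1319 at an unadjusted p under 0.05 and 201 called by DESeq2.

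Raet1d and Raet1e, ligands of the natural killer receptor NKG2D, rose. Raet1d stood at 15 ± 2.15 against 2.62 ± 0.599 CPM (edgeR adjusted p = 7.78e-04), and Raet1e at 10.5 ± 2.43 against 1.84 ± 0.27 CPM (adjusted p = 0.0026). Fgl1, a secreted liver protein, and Cxcl1 rose too. Falls included Rgs16, a regulator of G protein signals (log2 fold change -2.94 ± 0.48, edgeR adjusted p = 0.00346), Krt23 (-2.39 ± 0.42, adjusted p = 0.00438), Adgrv1, Serpina12 (-2.10 ± 0.31, adjusted p = 9.64e-04) and Txnip. Among CAR and PXR genes 0 of 29 tested members rose and 5 fell (1 and 6 adjusted over the list alone), with Cyp3a11, the main steroid and drug hydroxylase, at 546 ± 51.7 against 1331 ± 275 CPM (log2 fold change -1.29 ± 0.22, edgeR adjusted p = 0.00346). That list gave camera adjusted p = 2.20e-06, and 0.214 with an estimated correlation. In the female-biased list 0 of 34 tested members rose and 4 fell (0 and 9 adjusted over the list alone). This list gave camera adjusted p = 1.89e-05, and 0.214 with an estimated correlation, and the male-biased hydroxylases Cyp4a12a and Cyp4a12b also fell, with log2 fold changes of -1.49 ± 0.20 and -1.50 ± 0.20. In the acute phase list 3 of 31 tested members rose and 0 fell (11 and 0 adjusted over the list alone). The acute phase list gave camera adjusted p = 7.23e-07, and 0.412 with an estimated correlation. Hamp, hepcidin, had log2 fold change 1.02 ± 0.23, edgeR adjusted p = 0.0319. Of the cholesterol list 1 of 26 tested members rose and 0 fell (10 and 0 adjusted over the list alone), namely Sqle among all genes (log2 fold change 2.10 ± 0.48, edgeR adjusted p = 0.0439), with camera adjusted p = 5.43e-14, and 0.214 with an estimated correlation. The ribosomal protein genes were higher as a list, with a median log2 fold change of 0.31 (camera adjusted p = 4.02e-21, and 0.406 with an estimated correlation). The p53 target list passed with a median of 0.47 and 0 members called (camera adjusted p = 1.61e-07, and 0.214 with an estimated correlation). The clock list passed with -0.23 (camera adjusted p = 0.047, and 0.375 with an estimated correlation) and lost its call in 5 of 8 cases without 1 library (camera adjusted p up to 0.0863). The clock-linked gene Nampt fell (log2 fold change -1.07 ± 0.19, edgeR adjusted p = 0.00508). Ighg1 had 105 counts against 2, a ratio of 57.1 with an interval from 15.4 to 477.4. No list kept its call with an estimated correlation.

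The calls of 11 of the 27 named genes, Fgl1, Cxcl1, Txnip, Sqle, Scd1, Hamp, Apcs, Itih3, Ces2a, Hal and Susd4, were lost on leaving out at least 1 library. The count itself fell as low as 29, without 7-week replicate 3, and was 568 with only the 8 libraries in the fit.

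Restriction was set against free feeding in the wild type at 16 weeks, where amount, meal timing and fasting cannot be told apart. Called male-biased genes fell and most called female-biased genes rose, called ribosomal protein genes rose, and called proliferation genes fell. Only the male-biased list kept its call with an estimated correlation. Lepr (chromosome 4, 101717404 to 101815352), the leptin receptor, rose from 3.23 ± 1.03 to 117 ± 61.8 CPM (log2 fold change 5.19 ± 0.49, edgeR adjusted p = 4.91e-07), and Cyp4a12a, a male-biased hydroxylase, fell from 469.8 ± 87.6 to 20.2 ± 7.37 CPM (log2 fold change -4.54 ± 0.23, adjusted p = 2.26e-12). In all 1726 genes were called, 800 higher and 926 lower, and 562 of them by more than 1 on the log2 scale.

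In the male-biased list 0 of 29 tested members rose and 26 fell (0 and 26 adjusted over the list alone). The male-biased list gave camera adjusted p = 3.56e-56, and 3.14e-05 with an estimated correlation, so the call held. Elovl3, a fatty acid elongase (log2 fold change -6.48 ± 0.76, edgeR adjusted p = 1.06e-05), Mup8, Mup13 and Mup20 of the urinary protein cluster (-5.97, -5.80 and -3.77 on the log2 scale), the complement gene C6 (log2 fold change -4.13 ± 0.25, adjusted p = 4.89e-11) and Hsd3b5, a steroid dehydrogenase (log2 fold change -4.42 ± 0.47, adjusted p = 2.29e-06), all fell. Without restricted replicate 2 the log2 fold changes were -8.44 for Elovl3, -7.35, -7.12 and -4.50 for the Mup genes and -5.43 for Hsd3b5. Of the female-biased genes 16 of 34 tested members rose and 1 fell (19 and 1 adjusted over the list alone). The female-biased list gave camera adjusted p = 6.96e-08, and 0.121 with an estimated correlation. Sult3a2, a sulfotransferase gene near Sult3a1, had 1158 counts after restriction and 1 on free feeding, a ratio of 1122 with an interval from 201 to 44350, and Fmo6 had log2 fold change 8.16 ± 0.47, edgeR adjusted p = 1.46e-10, and 9.43 without freely fed replicate 2. Ghr fell (log2 fold change -0.97 ± 0.17, edgeR adjusted p = 3.19e-04). The acute-phase genes Saa1 and Saa2 fell, with log2 fold changes of -5.25 ± 1.39 and -5.18 ± 1.47, with 593.9 and 388.4 CPM in replicate 2 of the freely fed group, and lost their calls without it (-3.87 and -3.72, edgeR adjusted p = 0.0637 and 0.0926).

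Among ribosomal protein genes 68 of 77 tested members rose and 0 fell (75 and 0 adjusted over the list alone), with a median log2 fold change of 0.62 (camera adjusted p = 3.96e-35, and 0.274 with an estimated correlation). Rps12 stood at 109 ± 12.3 against 60.1 ± 4.31 CPM (log2 fold change 0.86 ± 0.14, edgeR adjusted p = 2.53e-04), Rpl3 had log2 fold change 0.74 ± 0.12, adjusted p = 2.26e-04 and Rps6 0.67 ± 0.12, adjusted p = 6.36e-04. In ribosome biogenesis 22 of 47 tested members rose and 0 fell (32 and 1 adjusted over the list alone). That list gave camera adjusted p = 9.72e-10, and 0.515 with an estimated correlation. The nucleolar protein Npm1 had log2 fold change 0.88 ± 0.16, edgeR adjusted p = 7.27e-04. Of the initiation factors 7 of 42 tested members rose and 1 fell (18 and 2 adjusted over the list alone). This list gave camera adjusted p = 2.60e-04, and 0.721 with an estimated correlation. Of the elongation and termination factors 4 of 14 tested members rose and 0 fell (10 and 0 adjusted over the list alone). This list gave camera adjusted p = 0.0103, and 0.515 with an estimated correlation. In the proliferation list 0 of 35 tested members rose and 15 fell (0 and 21 adjusted over the list alone). It gave camera adjusted p = 4.23e-11, and 0.274 with an estimated correlation. Ube2c (log2 fold change -2.44 ± 0.42, edgeR adjusted p = 3.38e-04) and the cell cycle factor E2f1 (log2 fold change -2.03 ± 0.35, adjusted p = 4.13e-04) were among its members. Sqle rose (log2 fold change 3.19 ± 0.52, edgeR adjusted p = 3.74e-04), and in the cholesterol list 3 of 26 tested members rose and 0 fell (3 and 0 adjusted over the list alone). The cholesterol list gave camera adjusted p = 9.20e-04, and 0.749 with an estimated correlation, and lost its call without restricted replicate 3 (camera adjusted p = 0.0769). Of the erythroid markers 0 of 6 tested members rose and 3 fell (0 and 5 adjusted over the list alone). The erythroid list gave camera adjusted p = 0.00113, and 0.274 with an estimated correlation, and Alas2, the heme synthesis enzyme of red cells, had log2 fold change -3.96 ± 0.81, edgeR adjusted p = 0.00291. The count fell to 1051 without restricted replicate 4, and was 986 with only these 8 libraries in the fit.

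**Figure D3:**
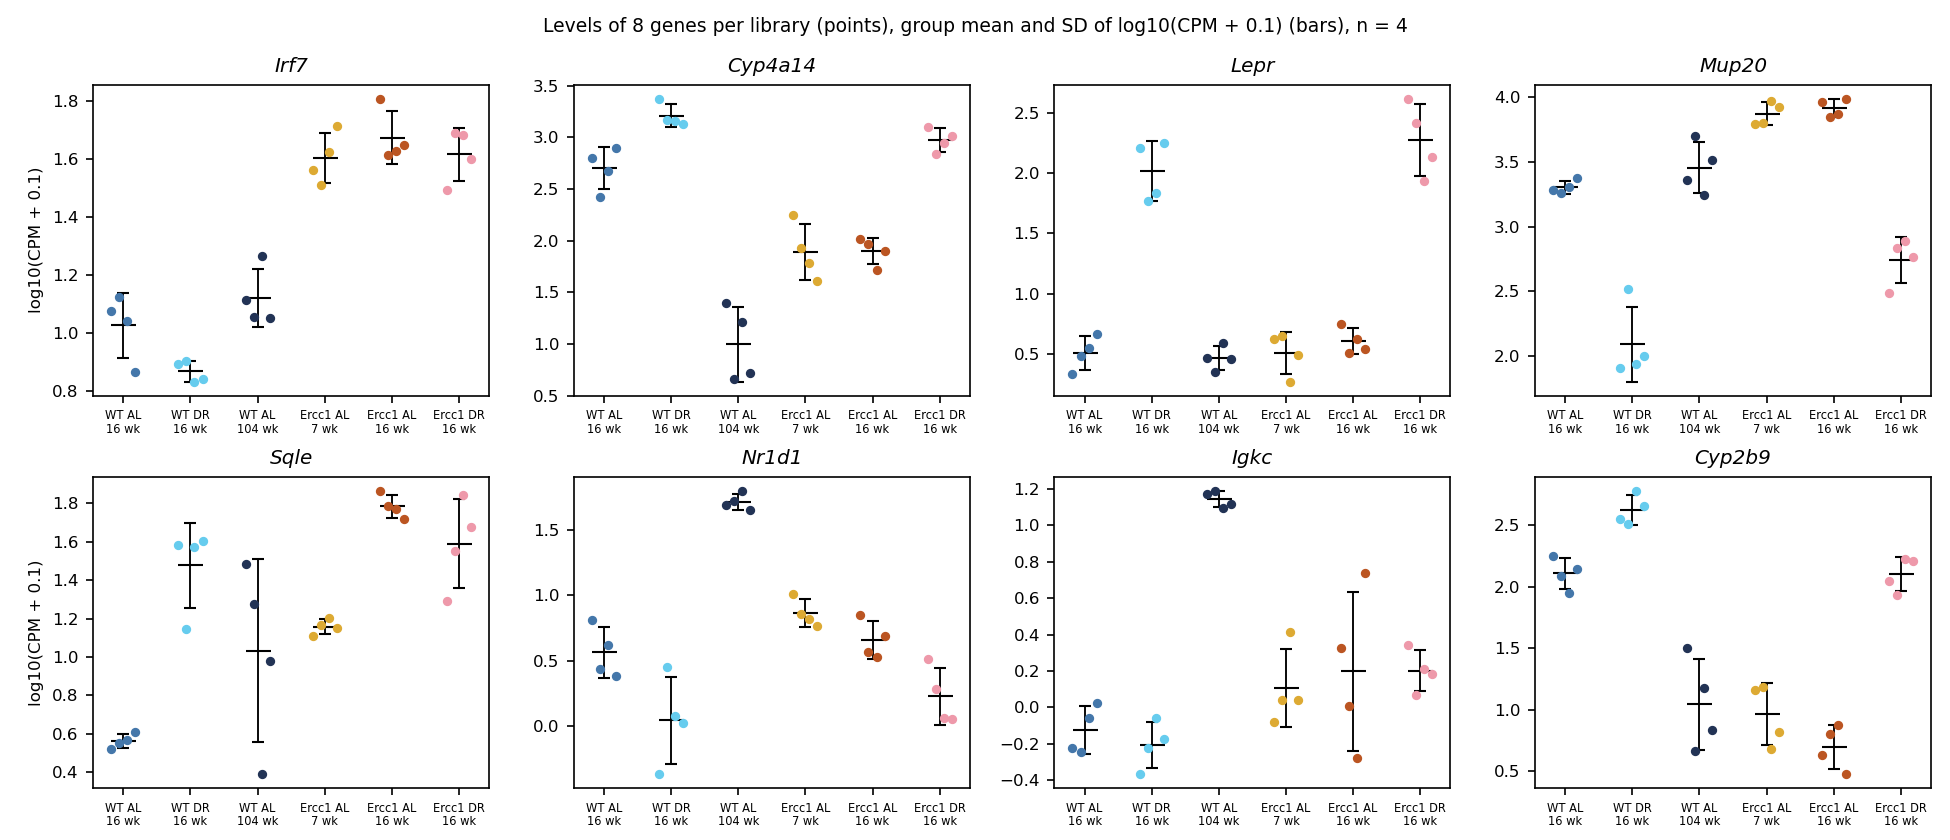
Levels of 8 genes per library as log10(CPM + 0.1) (points), with the mean and SD of each group (bars, n = 4). Irf7 is higher in the 3 mutant groups, Lepr in the 2 restricted groups and Igkc and Nr1d1 at 104 weeks, where Cyp4a14 is lowest.

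In the mutant at 16 weeks, restriction, known to extend its life, was set against free feeding, with amount and timing mixed. Called male-biased genes fell and most called female-biased genes rose, called genes of the unfolded protein response fell, and called genes of oxidative phosphorylation rose. The last 2 list calls were lost with an estimated correlation. Cyp2c39 rose from 60.0 ± 4.01 to 566 ± 21 CPM (log2 fold change 3.24 ± 0.21, edgeR adjusted p = 2.23e-10), and Cyp4a12a fell from 179 ± 24.4 to 12.8 ± 3.72 CPM (log2 fold change -3.81 ± 0.23, adjusted p = 6.66e-11). In all 1426 genes were called, 623 higher and 803 lower, and 647 of them by more than 1 on the log2 scale.

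In the male-biased list 0 of 29 tested members rose and 28 fell (0 and 29 adjusted over the list alone), and in the female-biased list 25 of 34 tested members rose and 2 fell (28 and 3 adjusted over the list alone). Both held, with camera adjusted p = 3.63e-77, and 1.54e-05 with an estimated correlation for the first and camera adjusted p = 2.61e-40, and 2.12e-05 with an estimated correlation for the second. The Mup cluster fell steeply, with Mup13 at log2 fold change -7.36 ± 0.82, edgeR adjusted p = 3.34e-06 and Mup20 at log2 fold change -3.83 ± 0.42, adjusted p = 2.12e-06, and so did Elovl3 (-6.61 on the log2 scale, -7.23 without restricted replicate 3) and Hsd3b5 (-5.17 ± 0.48, adjusted p = 2.32e-07). Cyp2b9 rose from 5.21 ± 2.03 to 132 ± 39.9 CPM (log2 fold change 4.67 ± 0.54, edgeR adjusted p = 5.25e-06) and Cyp4a14 from 82 ± 21.9 to 970.2 ± 248 CPM (log2 fold change 3.56 ± 0.52, adjusted p = 8.52e-05). Sulfotransferase genes rose from near 0. Sult3a2 had 330 counts after restriction and 0 on free feeding, at least 101.7-fold higher, and Sult3a1 had 912 against 2 (ratio 421.7, interval 116.4 to 3488). Sult2a2 had 728 against 3 (ratio 224.4, interval 76.5 to 1091), and Sult2a4 had 493 against 2 (ratio 228, interval 62.8 to 1888).

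In the unfolded protein response list 0 of 25 tested members rose and 17 fell (0 and 22 adjusted over the list alone). That list gave camera adjusted p = 4.06e-13, and 0.374 with an estimated correlation. Herpud1 had log2 fold change -1.59 ± 0.31, edgeR adjusted p = 0.00117 and Pdia3 stood at 282 ± 54.8 against 566 ± 109 CPM (adjusted p = 0.00232). Of the nuclear-encoded oxidative phosphorylation genes 15 of 67 tested members rose and 0 fell (24 and 0 adjusted over the list alone). The list gave camera adjusted p = 4.44e-09, and 0.847 with an estimated correlation. Atp5b stood at 1749 ± 94.1 against 1250 ± 69.2 CPM (log2 fold change 0.48 ± 0.10, edgeR adjusted p = 0.00136). Of the periportal markers 6 of 18 tested members rose and 3 fell (9 and 3 adjusted over the list alone). The periportal list gave camera adjusted p = 0.00285, and 0.374 with an estimated correlation. The urea cycle enzymes Ass1 had log2 fold change 1.07 ± 0.16, edgeR adjusted p = 4.70e-05 and Arg1 had log2 fold change 0.80 ± 0.13, adjusted p = 1.66e-04. Among proliferation genes 0 of 35 tested members rose and 8 fell (0 and 9 adjusted over the list alone). The proliferation list gave camera adjusted p = 0.0036, and 0.847 with an estimated correlation. The helicase subunits Mcm5 (-2.44 ± 0.38, edgeR adjusted p = 8.77e-05) and Mcm6 (-2.40 ± 0.43, adjusted p = 4.69e-04) were lower. In the ribosomal protein list 6 of 77 tested members rose and 0 fell (0 and 0 adjusted over the list alone). This list gave camera adjusted p = 1.15e-06, and 0.847 with an estimated correlation, and Rpl36, Rpl38 and Rpl36a each lost the call on leaving out at least 1 library (highest edgeR adjusted p = 0.0982, 0.106 and 0.143). In the p53 target list 1 of 30 tested members rose and 6 fell (2 and 8 adjusted over the list alone), with camera adjusted p = 0.0149, and 0.847 with an estimated correlation, and the call was lost without freely fed replicate 1 (camera adjusted p = 0.155). Ghr fell further (log2 fold change -1.32 ± 0.17, edgeR adjusted p = 5.25e-06), whereas Gdf15 (-0.32 ± 0.39, adjusted p = 0.67), Cdkn1a (-0.10 ± 0.54, adjusted p = 0.937) and Igf1 (-0.24 ± 0.14, adjusted p = 0.306) did not pass.

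Whether restriction acted differently in the 2 genotypes was tested as an interaction, the mutant's diet effect minus the wild type's. Enho, which encodes the hormone adropin, rose with restriction in the wild type and fell in the mutant, and Cd36, a fatty acid transporter, did the reverse. Enho went from 2.45 ± 0.892 to 5.91 ± 2.5 CPM in the wild type and from 14.3 ± 1.38 to 1.48 ± 0.528 CPM in the mutant (interaction -4.53 ± 0.52, edgeR adjusted p = 1.33e-05). Cd36 went from 86.3 ± 29.5 to 15.4 ± 4.67 CPM and from 46.8 ± 5.82 to 123 ± 25.9 CPM (interaction 3.89 ± 0.52, edgeR adjusted p = 1.93e-04). Such differences were found for 190 genes, 115 with a higher and 75 with a lower effect in the mutant.

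Sema5b, a semaphorin, had log2 fold changes with restriction of -4.19 in the wild type and 0.77 in the mutant (interaction 4.96 ± 0.75, edgeR adjusted p = 5.26e-04). Cux2, a female-biased transcription factor, had 1.83 and 5.94 (interaction 4.11 ± 1.03, edgeR adjusted p = 0.0492), Pcp4l1 2.67 and -0.08 (interaction -2.76 ± 0.45, adjusted p = 0.00106), and Sqle 3.19 and -0.52 (interaction -3.70 ± 0.69, adjusted p = 0.0065). The interaction was 5.63 for Sema5b without restricted wild-type replicate 2, and 4.85 and 3.48 for Cux2 without freely fed mutant replicate 4 and restricted mutant replicate 1. Female-biased genes had the larger log2 change in the mutant, since 10 of 34 had a higher and 2 a lower effect there (18 and 2 adjusted over the list alone), and this held with camera adjusted p = 8.20e-17, and 0.0102 with an estimated correlation. Cyp2c39 (2.49 ± 0.28, edgeR adjusted p = 1.33e-05), Cyp2c29 (2.26 ± 0.24, adjusted p = 1.33e-05) and Cyp2b9 (2.96 ± 0.67, adjusted p = 0.0295) were among them. Ribosomal protein genes had the smaller response in the mutant as a list, with a median interaction of -0.41 (camera adjusted p = 3.46e-13, and 0.562 with an estimated correlation). By group means the unfolded protein response fell more in the mutant, with a median interaction of -0.85 and 15 members lower when adjusted over the list alone (camera adjusted p = 2.58e-10, and 0.432 with an estimated correlation), and cholesterol genes rose in the wild type and fell in the mutant, with -0.99 (camera adjusted p = 9.83e-10, and 0.432 with an estimated correlation). Proliferation genes as a list fell less in the mutant, with a median interaction of 0.81 (camera adjusted p = 1.22e-04, and 0.562 with an estimated correlation). The count was 109 at the lowest without 1 library, 126 with only the 4 groups in the fit and 388 by DESeq2. The calls of Cux2, Cdc20, Cyp2b9, Hal, Pcx and Nudt7 were lost without at least 1 library.

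The age interaction took the mutant's change from 7 to 16 weeks minus the wild type's from 16 to 104 weeks. The spans differ in length, and the first may hold maturation. With age in the wild type, Cyp4a10 and Cyp4a14 fell and the clock gene Nr1d1 and Igkc rose, and these were not called in the mutant. The interaction was 5.26 ± 0.71, edgeR adjusted p = 1.96e-04 for Cyp4a14, 4.74 ± 0.47, adjusted p = 3.73e-06 for Cyp4a10 and -4.41 ± 0.55, adjusted p = 4.29e-05 for Nr1d1. Altogether 387 genes differed, 228 with a higher and 159 with a lower effect in the mutant.

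PPARalpha targets differed as a list, since 19 of 43 had a higher and 0 a lower effect in the mutant (28 and 0 adjusted over the list alone), and this held with camera adjusted p = 1.92e-33, and 0.0312 with an estimated correlation. Female-biased genes did so too, with 9 higher and 3 lower (12 and 3 adjusted over the list alone), which held with camera adjusted p = 4.40e-10, and 0.0341 with an estimated correlation. Both lists hold Cyp4a10, Cyp4a14 and Acot3, so they are not separate findings. Adgrf1, an adhesion receptor, rose at 104 weeks (3.38) and had -0.82 in the mutant (interaction -4.20 ± 0.54, edgeR adjusted p = 4.29e-05). Igkc (-3.57 ± 0.70, edgeR adjusted p = 0.00482), Il1r1 (-3.34 ± 0.69, adjusted p = 0.00974), Xbp1, a transcription factor of the unfolded protein response (-1.28 ± 0.25, adjusted p = 0.00482), and Hsd3b5 (-2.65 ± 0.55, adjusted p = 0.00877) had lower effects in the mutant, for Igkc -4.52 without mutant replicate 4 at 16 weeks. Macrophage markers had a median interaction of -0.82 (camera adjusted p = 2.22e-09, and 0.401 with an estimated correlation). Counts were 228 without mutant replicate 3 at 7 weeks, 755 with only the 4 groups in the fit and 646 by DESeq2. Ccne1, Cd5l, Ei24 and Eprs lost their calls without at least 1 library.

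Targets of the amino acid response factor ATF4 passed at 104 weeks, with a median log2 fold change of 0.44 (camera adjusted p = 0.0136, and 0.318 with an estimated correlation), and Asns, asparagine synthetase, rose there (log2 fold change 3.64 ± 0.76, edgeR adjusted p = 0.00288) and in the mutant at 16 weeks on free feeding (log2 fold change 3.74 ± 0.75, adjusted p = 0.00168), with 5.45 and 5.54 without freely fed wild-type replicate 3. In the restricted mutant against the restricted wild type, senescence genes had a median of 1.41 (camera adjusted p = 0.00427, and 0.224 with an estimated correlation), NRF2 and glutathione genes 0.36 (camera adjusted p = 0.026, and 0.713 with an estimated correlation), and cholangiocyte and progenitor markers 0.54 (camera adjusted p = 0.0158, and 0.367 with an estimated correlation). In the mutant at 16 against 7 weeks, endothelial markers had a median of -0.54 (camera adjusted p = 2.73e-06, and 0.412 with an estimated correlation), stellate cell markers -0.23 (camera adjusted p = 0.0027, and 0.483 with an estimated correlation), and gluconeogenesis and glycolysis genes -0.16 (camera adjusted p = 0.0109, and 0.412 with an estimated correlation). Bile acid genes had a median of -0.17 with restriction in the wild type (camera adjusted p = 0.045, and 0.515 with an estimated correlation). Without 1 of 8 libraries the NRF2 and bile acid lists each lost the call in 3 cases (highest camera adjusted p = 0.163 and 0.0994), and the ATF4, stellate cell and gluconeogenesis lists each in 1 (0.0693, 0.0779 and 0.0691). Lists that passed in none of the 8 contrasts were mitochondrial ribosomal proteins (lowest camera adjusted p = 0.057), nucleotide excision repair (0.167), the somatotropic axis (0.0527), T and NK cell markers (0.0866) and markers of other tissues (0.283).

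Log2 fold changes of pairs of comparisons were then correlated across genes, which are not independent replicates. Natural ageing and age in the mutant, which share no library, had r = 0.154 (jackknife SE 0.0893, Spearman 0.105), and 32 of the 43 genes called in both moved the same way. Restriction in the 2 genotypes, again without a shared library, had r = 0.570 (jackknife SE 0.0628, Spearman 0.451), with 499 of 519 shared calls in the same direction, where independent lists would share 39.3 rises and 58.6 falls against the 152 and 347 seen. The mutant's difference from wild type and natural ageing share the freely fed wild-type group. They had r = 0.364 (Spearman 0.374), where simulation without effects gave r = 0.491 ± 0.0145. Their covariance was 0.152 against 0.0518 ± 0.00219 simulated, and r was 0.238 to 0.270 with the shared libraries split 2 and 2. The split gave means of 32 shared rises and 74.8 shared falls, against 4.66 and 7.95 for independent lists. The mutant's difference and its response to restriction share the freely fed mutant group and had r = -0.163, with -0.505 ± 0.0157 simulated, a covariance of -0.0735 against -0.0483 ± 0.00211, and r from -0.141 to -0.0165 with the split. The mutant's difference and restriction in the wild type had r = 0.141 with 0.502 ± 0.0122 simulated, a covariance of 0.0623 against 0.0510 ± 0.00159, and r from 0.0482 to 0.0663 with the split.

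The last measure was the trend with gene span, for which no comparison passed after correction. The slope of log2 CPM on log10 gene span averaged -0.107 ± 0.0613 in the freely fed mutant at 16 weeks (SD, n = 4), 0.0874 ± 0.0602 in wild-type liver of that age and 0.0507 ± 0.0391 in the mutant at 7 weeks. The mutant differed from the wild type by -0.195 and from its own 7-week group by -0.158. Both had an exact permutation p = 0.0286, the smallest that 4 against 4 allows, and an adjusted p = 0.0857 over the 6 comparisons. Among the 25% of genes with the longest span in the mutant against wild-type comparison, 9.77% were called lower and 2.65% higher, and among the 25% with the shortest 2.30% lower and 7.09% higher. With restriction the slope differed by -0.0643 in the wild type (exact permutation p = 0.114) and 0.0387 in the mutant (exact permutation p = 0.600). Between 104 and 16 weeks it differed by -0.0727 (exact permutation p = 0.686), where replicate 2 at 104 weeks stood at -0.265 and the other 3 between 0.0638 and 0.142.

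**Figure D4:**
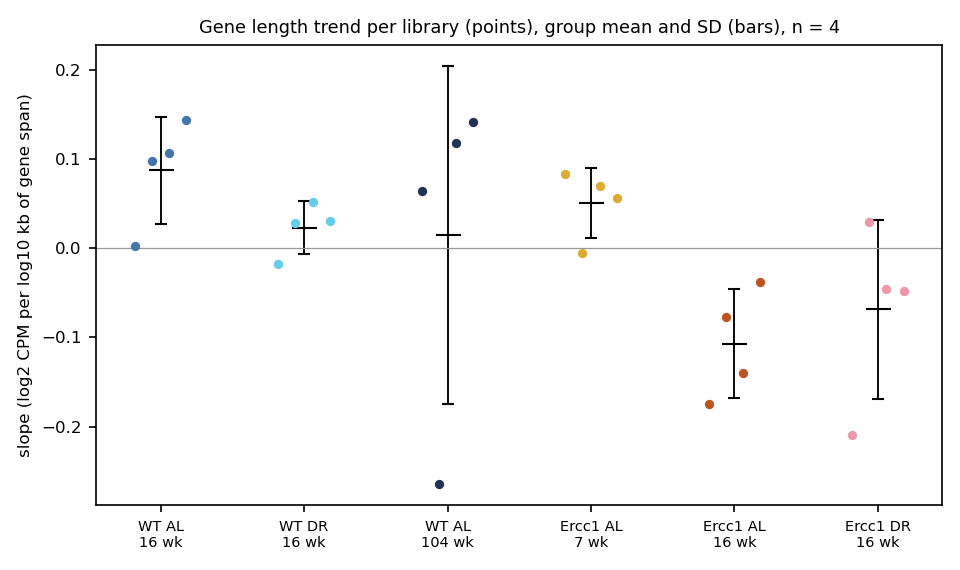
The slope of log2 CPM on log10 gene span (kb) for each library (points), with the group mean and SD (bars, n = 4). Freely fed mutant libraries at 16 weeks average -0.107 and wild-type libraries of the same age 0.0874, and replicate 2 at 104 weeks lies apart at -0.265.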

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

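The 2 tests of the Scd paralogs and the tests of clock phase and collection hour were chosen only after the result was seen, and the interval required of the odds ratio near Ercc1 was added then too.

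Single libraries stood far from the other 3 of their group, by the gap of the extreme library relative to the group's range, taken on CPM although log2 CPM had been planned. This held in 35 of 489 groups tested, or 7.16%, and chance gives about 1 in 20. In restricted wild-type replicate 4, the 20 most abundant genes took 39.4% of counts. Freely fed 16-week mutant replicate 1 had Cyp51 at 78.4, Eef1a1 at 3406, Irf7 at 64.3, Oas1a at 8.81, Phlda3 at 22.8, Rpl15 at 124 and Rpl36 at 194 CPM. Restricted wild-type replicate 2 had C6 at 17.2, Ckap2 at 0.143, Dnah1 at 0.358, Elovl3 at 3.8, Mup20 at 328 and Sqle at 13.9 CPM. Freely fed wild-type replicate 2 had Saa1 at 594, Saa2 at 388 and Scd1 at 3646 CPM. Restricted wild-type replicate 1 had Cyp4a14 at 2374, Fgf21 at 8.21 and Stard4 at 19.9 CPM. Freely fed 16-week mutant replicate 3 had Acot3 at 24.6 and Sult2a4 at 0.142 and restricted mutant replicate 2 had C1qc at 42.3 and Gdf15 at 36.2 CPM. Freely fed wild-type replicate 1 had C6 at 115 and Ccng1 at 18.7 and freely fed wild-type replicate 4 had Sult3a2 at 0.0685 CPM. Freely fed 16-week mutant replicate 2 had Cyp2c29 at 129 and 7-week mutant replicate 1 had Cdkn1a at 24.8 CPM. Restricted mutant replicate 4 had Gstt3 at 25.3 and 104-week wild-type replicate 1 had Fasn at 2338 CPM. Freely fed wild-type replicate 3 had Slc13a5 at 0.958, and restricted wild-type replicates 3 and 4 had Lrtm2 at 0.128 and Mlxipl at 152 CPM. Sult3a2, Lrtm2, Ckap2 and Sult2a4 had 1 or 2 counts over the group, all in that library, so their gap is full by construction and says nothing. These genes were tested because the report names them, and no cause was tested for any of these libraries.

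The effect of restriction differed between genotypes for 190 genes by the edgeR interaction. As mutant minus wild type on the log2 scale, the named genes were Cd36 3.89, Cdc20 3.29, Cux2 4.11, Cyp2b9 2.96, Cyp2c29 2.26, Cyp2c39 2.49, Enho -4.53, Hal 1.05, Nudt7 -1.40, Pcp4l1 -2.76, Pcx 0.71, Sema5b 4.96 and Sqle -3.70. The lists that passed camera, by their mean difference, were cytosolic ribosomal proteins -0.372, translation initiation factors -0.185, translation elongation and termination factors -0.309, aminoacyl-tRNA synthetases (cytosolic) -0.249, ribosome biogenesis -0.37, endoplasmic reticulum unfolded protein response -0.973, cytosolic heat shock response -0.543, male-biased liver genes -0.57, female-biased liver genes 1.35, cholesterol biosynthesis and uptake -1.08, fatty acid oxidation and PPARalpha targets 0.42, gluconeogenesis and glycolysis 0.18, oxidative phosphorylation (nuclear-encoded) 0.213, CAR and PXR drug metabolism 0.523, periportal hepatocyte markers 0.405, macrophage and Kupffer cell markers 0.464, erythroid markers 1.13 and proliferation 1.03. With an estimated correlation only the female-biased list kept its call (camera adjusted p = 0.0102), and the others had camera adjusted p = 0.432 to 0.573. On leaving out 1 library 5 of the 18 lost it at least once, male-biased genes with camera adjusted p = 0.77 without restricted wild-type replicate 2.

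The effect of age differed between genotypes for 387 genes by the same test. The named genes were Adgrf1 -4.20, Ccne1 -2.56, Cd5l -1.68, Cyp4a10 4.74, Cyp4a14 5.26, Cyp4a29 4.65, Cyp4a31 4.17, Ei24 0.66, Eprs -0.57, Hsd3b5 -2.65, Igkc -3.57, Il1r1 -3.34, Nr1d1 -4.41, Selenbp2 -2.06 and Xbp1 -1.28. The lists that passed camera were translation initiation factors -0.188, aminoacyl-tRNA synthetases (cytosolic) -0.305, ribosome biogenesis -0.227, endoplasmic reticulum unfolded protein response -0.436, cytosolic heat shock response -0.899, p53 target genes 0.648, male-biased liver genes -0.944, female-biased liver genes 0.707, fatty acid oxidation and PPARalpha targets 1.24, oxidative phosphorylation (nuclear-encoded) 0.142, acute phase response -0.358, macrophage and Kupffer cell markers -0.846, B and plasma cell markers -1.84 and proliferation 0.636. With an estimated correlation only the fatty acid oxidation and female-biased lists kept their calls, and the others had camera adjusted p = 0.0834 to 0.756. On leaving out 1 library 4 of the 14 lost it at least once, ribosome biogenesis in 8 and acute phase in 7 of 16 cases. This difference also holds the unequal spans and any maturation.

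All 35 splits of each pair of groups and 100 draws per interaction were fitted likewise, the real one included. Only the real one called as many genes, the lowest share 35 splits allow, unadjusted over counts. Draws regroup the genotype, so they cannot isolate the interaction. Mutant against wild type called 1262 genes on free feeding (highest other 2) and 2320 under restriction (highest other 857). Natural ageing called 1286 (highest other 11) and age in the mutant 87 (highest other 0). Restriction called 1726 in the wild type (highest other 13) and 1426 in the mutant (highest other 2). The 857 came from putting restricted mutant replicates 1 and 2 with restricted wild-type replicates 2 and 4, and what these share was not tested. Restricted mutant replicates 3 and 4 were a close pair (chi-square per degree of freedom 8.315, 29.56 to 54.18 for the group's other pairs). The tests treat all 4 as equally independent. The interactions called 190 with diet (highest other 153) and 387 with age (highest other 152).

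Called genes, Igsf23 among them, lay around Ercc1 in the freely fed mutant. Within 10 Mb, leaving out Ercc1 and Igsf23, 27 of 208 tested genes were called, 12.98% against 9.89% elsewhere. Of the 27, 23 moved the same way under restriction, a share not measured elsewhere. Cyp2b and Sult2a paralogs among them may share reads, but Fisher tests count each as a gene. DNA of another strain or of the targeted cells, kept around the mutated gene, may add to these calls. The one-sided Fisher p was 0.09 with an odds ratio of 1.36 (95% interval 0.868 to 2.06). These point values met the bound set beforehand against that explanation. Still, it cannot be told apart, as the interval passes 2 and 56 genes were called nearby under restriction (26.9% against 18.1%, one-sided Fisher p = 0.00123, odds ratio 1.66). A chance cluster also stays open, at the 78.1 percentile of 311 windows on other autosomes, and at the 95.5 percentile under restriction.

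Scd1, Scd2, Scd3 and Scd4, desaturase paralogs, fell together in the freely fed mutant. The log2 ratio of each paralog to Scd1 had an SD of at most 0.064 over 24 libraries, while log2 Scd1 itself had an SD of 1.33, so reads shared between paralogs may account for the common fall. The ratios of other called lipogenic genes to Scd1 were less even, with a median SD of 0.885, which argues against separate genes under the control these share. The fall of at least 1 Scd gene is not in question, but which one cannot be read from these counts.

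Clock genes shifted at 104 weeks, and the evening arm rose relative to the morning arm by 2.4 on the log2 scale (evening mean 1.18, morning mean -1.22). Of the named members, 3 of 5 morning genes fell, led by Arntl, and 4 of 10 evening genes rose, led by Nr1d1 and Dbp. Another clock phase at collection is a candidate explanation, and a single deviating library is argued against, as the difference was at least 2.04 without any 1 library at 104 weeks. Whether the hour of collection differed between ages cannot be told apart from an effect of age, since the labels give 0 lines with an hour. The arms also differed with restriction, by -1.85 in the wild type and -1.25 in the mutant, where meals were timed. Between mutant and wild type they differed by 0.753 on free feeding and 1.35 under restriction, the same way as with age in the wild type, and by -0.359 between the mutant at 16 and 7 weeks, the other way.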

How the results depend on the processing

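No alternative was added after the data were seen. Over all settings, 5681 of 5940 values of named genes kept their direction and side of the threshold (95.6%), 239 lost the call, 20 gained it and 0 reversed. For gene lists this held in 2311 of 2623 (88.1%), with 310 calls lost and 2 reversed. Camera with an estimated correlation kept 11 of the 125 list calls and fry kept 61, so most list calls rest on the preset correlation.

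With an absolute log2 fold change above 1 required, stricter by construction, counts were 594 and 998 for mutant against wild type on free feeding and under restriction. They were 589 and 57 for age in the wild type and mutant, and 562 and 647 for restriction likewise.

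With only the contrast's groups fitted, mutant against wild type had 2202 on free feeding and 877 under restriction. The order, 1262 and 2320 in the main fit, was reversed and stays open. Age in the mutant had 568, restriction in the wild type 986, and the diet and age interactions 126 and 755. DESeq2 called 201 for age in the mutant, and 388 and 646 for the interactions. The cause was not tested.

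Leaving out 1 library at a time, counts ran from 871 to 1082 and from 1804 to 2256 for the mutant against wild type on free feeding and under restriction. For age they ran from 792 to 1533 in the wild type and 29 to 76 in the mutant, and for restriction from 1051 to 2009 in the wild type and 1053 to 1414 in the mutant. The interactions ran from 109 to 225 with diet and 228 to 505 with age. The lowest values came without freely fed wild-type replicate 3 at 16 weeks (792), 7-week mutant replicate 3 (29 and 228), restricted wild-type replicate 4 (1051) and freely fed wild-type replicate 4 at 16 weeks (109). Other counts moved by over 1.5 times were 1145, 125 and 257 without freely fed wild-type replicate 3 at 16 weeks, for restriction and the 2 interactions. Without 16-week mutant replicates 1 and 3 the diet interaction had 113 and 120, and without replicates 1, 3 and 4 age in the mutant had 40, 57 and 40. Without 7-week mutant replicates 1, 2 and 4 it had 33, 43 and 56. The cause was not tested.

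Reversed were 2 lists in the mutant at 16 against 7 weeks. The mean of B and plasma cell markers was -0.0185 with only those 2 groups in the fit, and that of ribosome biogenesis -0.0178 without 16-week mutant replicate 1, in a leave-one-out range up to 0.188. The cause was not tested.

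Similarity of log2 fold changes moved with the genes used. Among genes changed in at least 1 of the 2 comparisons, r was 0.275 between age in the wild type and in the mutant and 0.680 between restriction in the 2 genotypes. With no filter on low counts, r was 0.258 for the 2 restrictions, -0.330 for the mutant's difference and restriction in the mutant, and 0.330 for the mutant's difference and restriction in the wild type. With the shared libraries split 2 and 2, r was 0.256 for the mutant's difference and natural ageing and -0.0764 for the mutant's difference and restriction in the mutant. The cause was not tested.

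The trend with gene span passed in none of its 3 other settings with all libraries, with the lowest exact permutation adjusted p = 0.0571 when exonic length and mean level were added as terms, and leaving out 1 library could not pass by construction.

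Replicate numbers do not pair the libraries, with correlations of same-numbered effects from -0.222 to 0.316, and with them as a block the counts were 1323, 2336, 1303, 70, 1758, 1461, 184 and 388 in the order of the report. At this depth Ercc1 itself had 17 to 94 counts per library, which limits the test of its fall.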

Other observations

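Genes below were chosen after their values were seen, though the naming rule had picked some too.

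All 12 mutant libraries lay above all 12 wild-type ones in 64 genes and below in 36, whatever the age or diet. Ungrouped libraries would give 0.00939 both ways, but groups differ, so such values are no test. Pls1, an actin-bundling protein, stood at 13.7 ± 6.01 against 0.920 ± 0.761 CPM (SD, 12 libraries each). Ctsc, a lysosomal protease, stood at 23.5 ± 4.45 against 61.2 ± 9.93 CPM. The median span was 17.5 kb for the genes above and 93.9 kb for those below.

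All 8 restricted libraries lay above the 16 freely fed ones in 36 genes and below in 135, with 0.0345 both ways if ungrouped. Lepr stood at 170.9 ± 119 against 3.36 ± 1.00 CPM, and Fmo6, Cyp39a1, Sybu and Angptl8 were also above, while Slc22a7 and Elovl3 were below.

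The 4 wild-type libraries at 104 weeks lay above the other 20 in 135 genes and below in 110, with 2.39 both ways if ungrouped. Above were Ighm, Igkc, Grm8, E2f7, Ntrk2, Serpina12, Nr1d1 and Dbp, and below were Arntl, Cry1, Fmo2, Cyp4a10 and Cyp3a44.

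Cyp26a1 was higher in the mutant on free feeding (log2 fold change 1.82 ± 0.28, edgeR adjusted p = 1.08e-04), at 104 weeks (1.31 ± 0.29, adjusted p = 0.00396), and after restriction in the wild type (1.90 ± 0.28, adjusted p = 8.05e-05) and the mutant (1.53 ± 0.27, adjusted p = 3.02e-04).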
